A study of Homo sapiens with 18 samples.

How the data were processed

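RNA was taken from MCF-10A cells after 8 days in Matrigel, and stranded mRNA libraries were sequenced as paired 101-base reads on a HiSeq instrument, per the labels' protocols. The deposited table holds raw, not normalised, counts per gene for 18 samples, 1 column per sample, and the authors' deposited counts were whole numbers with column totals of 36426438 to 70515965. Trimmomatic 0.36, STAR 2.5.1b, Subread, featureCounts and the build GRCh37 are named in the submitters' processing notes, without role or order. Whether counting used strand, and whether read pairs or reads were counted, is not given in the sources used here. Antisense and overlapping genes, paralogs and pseudogenes can therefore share or lose reads, which bears on STARD13-AS, FDPS with RUSC1-AS1, SRSF9 with GATC, MIS18A-AS1, KRT81 with KRT86, histone genes, HLA-B and PCDHGA11. Gene names and types came from GENCODE release 29 on another build, matched by gene ID without coordinates: 55951 of 60252 IDs were named, and the 4301 without a name took 0.152% to 0.193% of counts per sample. The overlaps stated for named genes are those of that annotation.

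Groups were taken from the construct in the labels, and replicate numbers from the sample titles. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where stated otherwise. The plan was to sum samples that share a library ID where their mean chi-square per gene (genes with 20 or more counts over the pair) was under 1.5. The 4 lane pairs had means of 3.82 to 9.06 and medians of 1.13 to 1.81, so that limit was not met, while the other 14 pairs had means of 58.8 to 318 and medians of 5.02 to 22.0. The lanes were summed all the same, because the labels give each pair a single library ID and barcode, lane pairs differed far less than any others, and repeat runs of a library are not replicates. This departure from the plan was decided after the chi-squares, the correlations between samples, their principal components and the factor levels per sample were seen, and before any test between groups. By the letter of the plan, the 18 samples would have entered as separate replicates. Since that choice, like the tool and the groups fitted, changes the number of genes called, counts from the 18 samples stand beside those from the 14 libraries in each contrast with Control.

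Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Counts of the 14 libraries were normalised by TMM and filtered with filterByExpr (minimum count 10), which left 21326 genes. All 6 groups entered a single edgeR quasi-likelihood model with group and label set as terms, where the label set parts the 4 summed libraries, whose descriptions carry a library ID, from the 10 libraries with numeric labels. The model left 7 residual degrees of freedom, and the common biological coefficient of variation was 0.318. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in the 5 contrasts with Control, an F test over the 5 overexpression groups and 10 direct contrasts. Log2 fold changes are adjusted for label set, so they can differ from the ratio of mean CPM.

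For 30 fixed gene lists, camera with a preset correlation of 0.01 was run on each contrast with Control and adjusted over all 150 tests, beside camera with an estimated correlation and fry. Neither direction nor p of fry compares a list with other genes. CD24, IL8, BOP1, HIST1H4B and PECAM1, members of the lists, were not matched by symbol. The rule for named genes took the factors, the 8 genes with the largest rise and the 8 with the largest fall past the threshold, and the 8 with the smallest p in the F test, factors left out. A rise or fall needed a mean CPM of at least 3, every library of the group on the same side of every Control library, and an approved-style symbol. Up to 4 members past the threshold were taken from each list with a camera call or with 3 or more changed members. Since edgeR called few genes, the same rule was also applied to DESeq2 calls, a choice made after the edgeR counts were seen; a selection of those genes is described, and some that the rule took are not reported here. Genes outside the rule were named after their values were seen, as stated beside them.

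On simulated counts with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold per contrast, built from the means and library sizes of the real data, edgeR recovered 0% of genes changed 1.5-fold, 4.48% to 11.9% of those changed 2-fold and 57.6% to 68.2% of those changed 4-fold over the 5 contrasts, with 0 to 3 false calls each. In 10 simulated sets without change, drawn for the 21326 filtered genes alone, DESeq2 called a median of 23.5 and at most 45 genes per contrast, pooled over the 5 contrasts. Both simulations drew each gene independently, so they do not carry shifts shared by many genes of a library. Alternatives covered normalisation, filters, tool, label set, replicate block, separate samples, the groups fitted, a fold threshold of 1.5 and leaving out each library. Before the full set of alternatives was run, edgeR fits of the 14 libraries and of the 18 samples, each with the label set, without it and with the replicate block, and DESeq2 and voom on the 14 libraries had been looked at.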

Results

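Gene expression was measured by stranded mRNA sequencing in MCF-10A, an immortalised, non-tumorigenic human mammary epithelial cell line, after 8 days of three-dimensional culture in Matrigel, a basement membrane gel. The cells stably carried a retroviral vector that was empty (Control) or held the coding sequence of an SR protein (SRSF2, SRSF4, SRSF6 or SRSF9) or of the SR-like protein TRA2B, all regulators of pre-mRNA splicing. The question set by the design was how gene expression differed between each overexpression (OE) group and Control. Splicing was not analysed here. The 18 samples fell into 6 groups of 3, and each held 36426438 to 70515965 counts over 60252 genes. In Control, SRSF4-OE, SRSF6-OE and TRA2B-OE, replicates 1 and 2 carried the same library ID and barcode and differed only in sequencing lane. The mean chi-square per gene between such lane pairs was 3.82 to 9.06, above sampling noise alone, against 58.8 to 318 for the other 14 pairs of samples within a group. A limit of 1.5 set beforehand for treating them as equal was not met, but because they were runs of a single library the lanes were summed and counted as 1 replicate, which left 14 libraries of 42959069 to 121601376 counts. These were 3 libraries each for SRSF2-OE and SRSF9-OE and 2 each for the other 4 groups. All libraries of SRSF2-OE and SRSF9-OE carried numeric labels, while the other 4 groups each held both label sets. The contrasts of SRSF2-OE and SRSF9-OE with Control therefore rest in part on the label set term of the model. Their mean CPM covers a single label set, and that of Control covers both. Levels are given in CPM, counts scaled to the normalised library size, as mean ± SD over libraries, and log2 fold changes as estimate ± standard error from edgeR's quasi-likelihood fit.

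The introduced factors were examined first, in every library. SRSF9 stood at 609 ± 241 CPM (n = 3) in the libraries labelled SRSF9-OE and 93.9 ± 2.07 CPM (n = 2) in Control, a log2 fold change of 2.71 ± 0.33. SRSF4 stood at 177 ± 13.9 CPM (n = 2) in the libraries labelled SRSF4-OE and 83.4 ± 17.1 CPM in Control, a log2 fold change of 1.10 ± 0.15. SRSF2 was 307 ± 91.2 CPM (n = 3) against 190 ± 19.7 CPM, a log2 fold change of 0.80 ± 0.24, and TRA2B was 174 ± 38.3 CPM (n = 2) against 105 ± 0.695 CPM, a log2 fold change of 0.71 ± 0.16. In the other 4 contrasts, TRA2B also lay 0.41 to 0.63, SRSF2 0.33 to 0.46 and SRSF4 0.26 to 0.30 log2 units above Control, none past edgeR's test. SRSF6 was not detectably higher in the libraries labelled SRSF6-OE than in Control, at 350 ± 94.5 CPM (n = 2) against 320 ± 114 CPM and a log2 fold change of 0.15 ± 0.22. That value ran from -0.014 without Control replicate 3 to 0.35 without Control replicates 1-2. SRSF6 was 0.36 log2 units above Control in both SRSF2-OE and SRSF4-OE.

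With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all 21326 genes tested, none of the 5 factors passed in its own group. The adjusted p was 0.233 for SRSF2, 0.109 for SRSF4, 0.718 for SRSF6, 0.158 for SRSF9 and 0.169 for TRA2B. Adjusted over the 5 factors of each contrast alone, it was 0.040, 1.0e-04, 0.649, 4.5e-05 and 0.0048. DESeq2, adjusted over all genes, gave 0.092, 1.1e-07, 0.695, 7.2e-11 and 0.0062. In edgeR, SRSF9 passed without SRSF9-OE replicate 1 (log2 fold change 2.98, adjusted p = 0.0041) and SRSF4 when only the 4 libraries compared were fitted (1.12, adjusted p = 0.011). The library labelled SRSF2-OE replicate 1 held 214 CPM of SRSF2, and the library labelled TRA2B-OE replicate 3 held 147 CPM of TRA2B, both within the range of libraries of other labels (176 to 272 and 105 to 168 CPM, each without the other of these 2 libraries). Counts do not separate the introduced coding sequence from the endogenous gene. Since SRSF6 was not detectably raised, and those 2 libraries showed little of their factor, each group is referred to by its label.

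**Figure D1:**
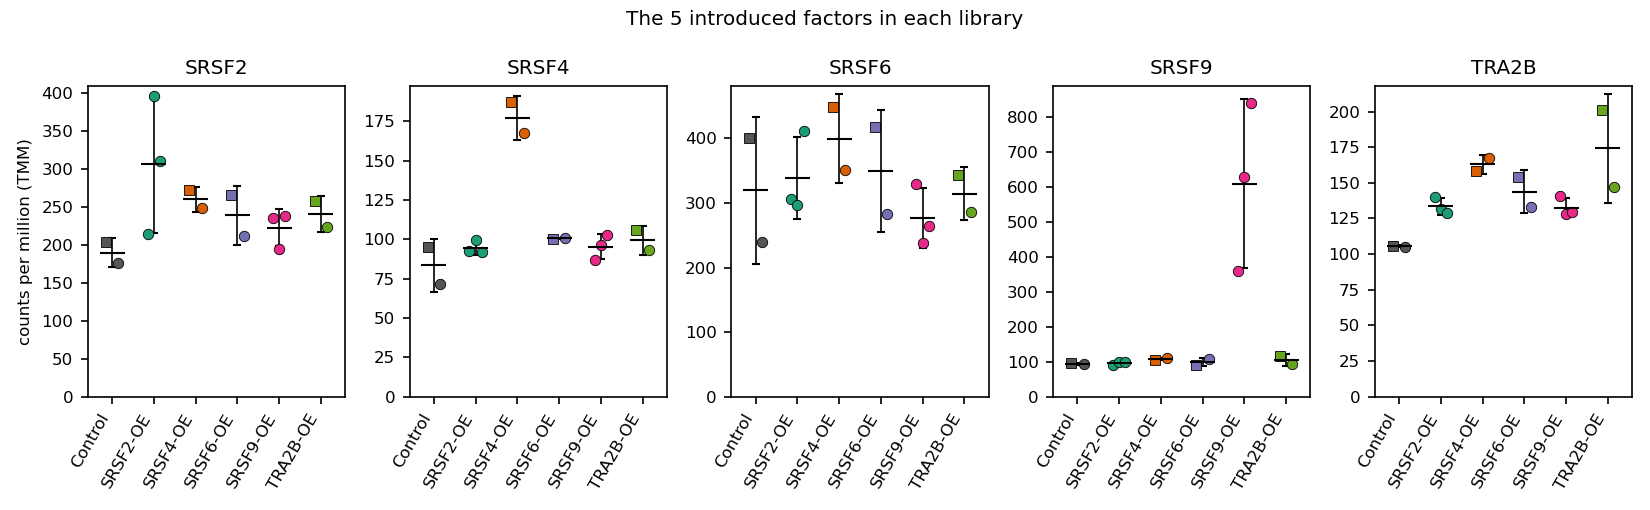
Level of each introduced factor in CPM (y axis, linear, from 0) in the 14 libraries by label (x axis). Circles are libraries of 1 sample, squares are libraries summed over 2 lanes, horizontal lines are means and whiskers are SDs; SRSF9 (609 against 93.9 CPM) and SRSF4 (177 against 83.4 CPM) separate from Control, and SRSF6 (350 against 320 CPM) does not.

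The libraries did not group by label alone. On log2 CPM, the library most correlated with each of the 14 carried the same label in 5 cases. TRA2B-OE replicate 3 lay closest to SRSF2-OE replicate 1 (r = 0.989 across genes), Control replicate 3 to SRSF9-OE replicate 1 (r = 0.991) and the summed SRSF4-OE library to the summed SRSF6-OE library (r = 0.989), while libraries of the same label correlated at 0.952 to 0.985. Genes are not independent replicates, so these values describe the libraries only. Mitochondrially encoded genes took 6.45% to 16.4% of counts per library, with the highest shares in SRSF2-OE replicate 1 (16.4%) and TRA2B-OE replicate 3 (14.3%).

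**Figure D2:**
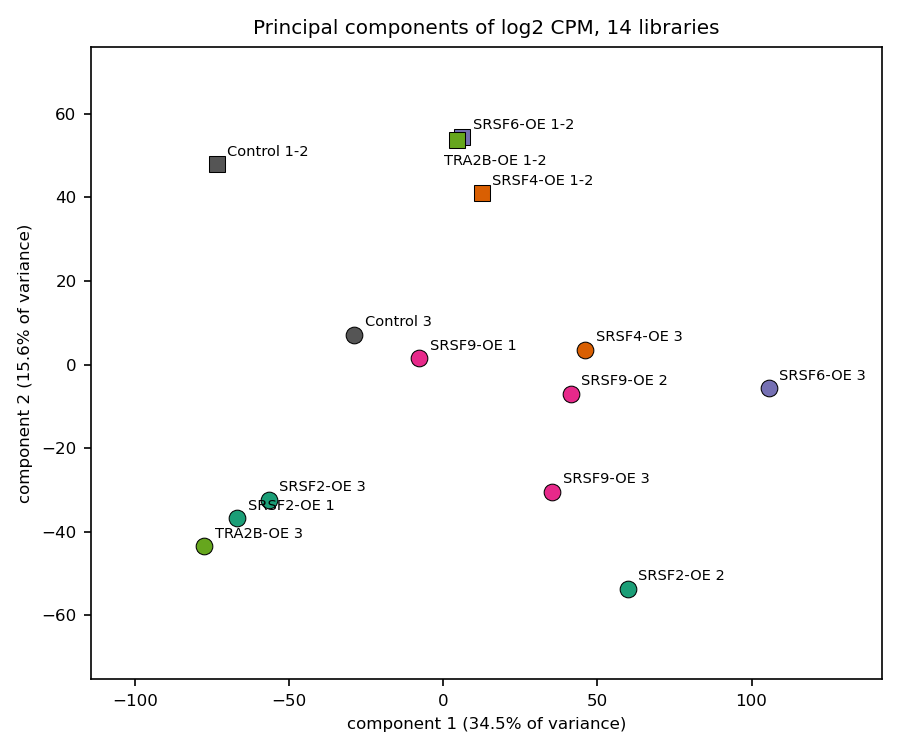
Principal components of log2 CPM over the 14 libraries, with component 1 (34.5% of variance) on the x axis and component 2 (15.6%) on the y axis. Squares are the 4 libraries summed over lanes and circles the other 10; the squares lie at the top of component 2 together, and TRA2B-OE replicate 3 lies beside SRSF2-OE replicates 1 and 3.

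In the libraries labelled SRSF2-OE, the genes furthest above Control were BAIAP2L2 (log2 fold change 2.88 ± 0.82), the hair keratin gene KRT81 (2.73 ± 0.73, 560 ± 387 against 71.8 ± 34.3 CPM) and PHEX (2.54 ± 0.63), by DESeq2 calls. The mesothelin gene MSLN stood at 303 ± 140 against 87.5 ± 22.2 CPM, and FADS2, a fatty acid desaturase gene, was 2.25 ± 0.50 log2 units higher. The tight junction gene CLDN1 lay below Control at a log2 fold change of -3.81 ± 0.67 (8.55 ± 2.49 against 122 ± 64.0 CPM). BIRC3, which encodes an inhibitor of apoptosis, and SOD2, which encodes mitochondrial superoxide dismutase, lay at log2 fold changes of -1.90 ± 0.27 and -1.73 ± 0.36. The stress transcription factor gene ATF3 was at -4.22 ± 0.94, but its Control libraries differed widely (79.3 and 6.71 CPM).

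Cholesterol and sterol synthesis genes lay above Control in 20 of 21 members in SRSF2-OE, with a median log2 fold change of 0.87 (camera adjusted p = 1.1e-13, and adjusted p = 0.482 with an estimated correlation). DHCR7 (1.78 ± 0.42), MVD (1.69 ± 0.31), INSIG1 (1.58 ± 0.46) and FDPS (1.15 ± 0.20) passed in DESeq2; edgeR called 0 members over all genes and 12 adjusted over the list alone, and DESeq2 called 5. DNA replication genes were higher in 26 of 26 members (median 0.73, camera adjusted p = 1.4e-07), mitotic genes in 30 of 30 (median 0.62, camera adjusted p = 0.016) and ribosome biogenesis genes in 24 of 27 (median 0.36, camera adjusted p = 3.2e-06), of which NOP56 (1.06 ± 0.17) passed in DESeq2. With an estimated correlation these had adjusted p = 0.704, 0.822 and 0.704. The Control libraries lay far apart in the mean log2 CPM of mitotic (3.70 and 4.95) and replication genes (3.13 and 4.01). SRSF2-OE replicate 2 (3.94 and 3.69) lay between them, and SRSF2-OE replicates 1 and 3 above both. Epithelial junction genes were lower in 21 of 25 members (median -0.41, camera adjusted p = 1.1e-04), interferon-stimulated genes in 24 of 34 (median -0.40, camera adjusted p = 8.5e-04, with IFIT5 at -0.64 ± 0.16) and NF-kB and cytokine genes in 17 of 27 (median -0.23, camera adjusted p = 0.039). Their adjusted p was 0.482, 0.704 and 0.822 with an estimated correlation. Adjusted over the list alone, edgeR passed 1 ribosome biogenesis gene, 1 junction gene (CLDN1), 2 NF-kB genes (BIRC3 and SOD2) and 0 replication, mitotic or interferon-stimulated members, of which DESeq2 called 0, 0 and 1.

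No single gene passed edgeR's test for SRSF2-OE against Control (0 of 21326, smallest adjusted p = 0.127), while 2849 genes had an unadjusted p under 0.05, where 1066 are expected by chance. Limma-voom called 0, DESeq2 called 236 genes higher and 215 lower, and edgeR on all 18 samples as separate replicates called 714 and 631. The edgeR count was 69 without SRSF2-OE replicate 1, 2 without Control replicate 3 and 46 without the libraries labelled SRSF2-OE replicate 1 and TRA2B-OE replicate 3.

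In the libraries labelled SRSF4-OE, the growth factor carrier gene FGFBP1 (151 ± 85.0 against 13.0 ± 16.5 CPM), KRT81 (log2 fold change 3.73 ± 0.77), its neighbouring keratin gene KRT86 (3.47 ± 0.85) and THBS1, a matrix glycoprotein gene (712 ± 335 against 81.3 ± 92.0 CPM), were above Control. CD1D, CCBE1 and RAPGEF3 were 4.41 ± 1.35, 3.62 ± 0.96 and 3.67 ± 1.04 log2 units higher. The cell adhesion gene CNTN3 (-5.98 ± 1.70), the interferon-induced BST2 (-5.24 ± 1.70), ZNF22 (-4.73 ± 1.42), the complement gene C1R (-4.27 ± 1.18) and ATF3 (-4.60 ± 1.01) were below it. All of these passed in DESeq2, and none did in edgeR. Among SR genes, SRSF7 (0.59 ± 0.13) and TRA2B (0.63 ± 0.16) were higher and SRSF12 (-1.84 ± 0.36) lower by DESeq2.

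Mitotic genes lay above Control in 30 of 30 members in SRSF4-OE (median log2 fold change 1.33, camera adjusted p = 2.3e-11), with AURKA at 1.71 ± 0.52 and TPX2 at 1.69 ± 0.51, but adjusted p = 0.704 with an estimated correlation. DNA replication genes were higher in 26 of 26 (median 0.97, camera adjusted p = 1.5e-13), including E2F1 (2.25 ± 0.71), UHRF1 (2.24 ± 0.55) and CDC45 (2.09 ± 0.59), ribosome biogenesis genes in 27 of 27 (median 0.51, camera adjusted p = 3.0e-10) and sterol synthesis genes in 21 of 21 (median 0.83, camera adjusted p = 5.6e-11). With an estimated correlation, adjusted p = 0.704 for replication and ribosome biogenesis and adjusted p = 0.666 for sterol synthesis. Keratinocyte cornification genes were higher in 22 of 28 (median 1.62, camera adjusted p = 2.0e-04) and matrix protease genes in 18 of 23 (median 1.01, camera adjusted p = 7.0e-04, with PLAT, tissue plasminogen activator, at 1.43 ± 0.31); both had adjusted p = 0.704 with an estimated correlation. Immediate early and EGFR feedback genes were higher in 21 of 28 members (median 0.82, camera adjusted p = 0.017), TGF-beta response genes in 18 of 21 (median 0.33, camera adjusted p = 0.021), glycolysis and hypoxia genes in 21 of 27 (median 0.47, camera adjusted p = 0.0017), SR genes in 10 of 13 (median 0.36, camera adjusted p = 0.016) and hnRNP genes in 17 of 22 (median 0.16, camera adjusted p = 0.036). With an estimated correlation, these 5 lists had adjusted p = 0.773, 0.704, 0.736, 0.704 and 0.704. The SR list holds SRSF4 itself, and the only immediate early member that DESeq2 called, ATF3, was lower. Interferon-stimulated genes were lower in 30 of 34 members (median -0.70, camera adjusted p = 1.1e-04), MHC class I genes in 8 of 9 (median -0.45, camera adjusted p = 0.041, with HLA-B at 5.25 ± 2.97 against 28.5 ± 5.33 CPM) and replication-dependent histone genes in 9 of 10 (median -0.65, camera adjusted p = 0.038). Their adjusted p was 0.704, 0.704 and 0.746 with an estimated correlation. Adjusted over the list alone, edgeR passed 11 ribosome biogenesis, 9 DNA replication, 7 sterol synthesis and 6 SR genes, and 0 mitotic, cornification, interferon-stimulated or histone genes, against 0 in every list over all genes. DESeq2 called 3, 5, 4 and 4 of the former and 2, 0, 1 and 0 of the latter. Of the SR genes, 1 of the 6 and 1 of the 4 were lower than Control.

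No gene passed edgeR's test for SRSF4-OE against Control (0 of 21326, smallest adjusted p = 0.073), with 3172 at an unadjusted p under 0.05. Limma-voom called 0, DESeq2 called 297 genes higher and 260 lower, and edgeR on 18 separate samples called 1933 and 1532. The edgeR count was 2 without Control replicate 3, 24 without SRSF2-OE replicate 1, 3 without SRSF2-OE replicate 2, 88 without the libraries labelled SRSF2-OE replicate 1 and TRA2B-OE replicate 3, and 2504 when only the 4 libraries compared were fitted.

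In the libraries labelled SRSF6-OE, STARD13-AS, an RNA transcribed opposite to and within the STARD13 gene, rose from 0.244 ± 0.043 CPM in Control to 164 ± 163 CPM (n = 2, 48.8 and 280 CPM), a log2 fold change of 9.21 ± 0.96 and the only gene that passed edgeR's test (adjusted p = 0.041). The calcium-binding protein gene CALB1 (769 ± 929 against 6.48 ± 0.226 CPM), the matrix gene TNC (144 ± 158 against 3.02 ± 3.56 CPM) and CDH4, a cadherin gene (27.4 ± 22.8 against 0.711 ± 0.465 CPM), were higher in DESeq2. The SD lay above the mean for CALB1 and TNC, so most of their level came from a single SRSF6-OE library, and near the mean for CDH4. Fibronectin, FN1, stood at 384 ± 84.1 against 14.3 ± 3.81 CPM, and the metalloproteinase genes MMP1 and MMP10 at 10.8 ± 15.1 and 8.45 ± 11.9 CPM against 0.017 ± 0.0031 and 0.0038 ± 0.0054 CPM. For MMP1 and MMP10 the SD lay above the mean by a larger share, so nearly all of their level came from a single SRSF6-OE library. The chemokine gene CXCL14 (-4.47 ± 1.43), IGFBP3 (-3.26 ± 0.95) and SELENOP (-3.10 ± 1.01), a selenium transport gene with which CCDC152 (-3.21 ± 1.04) shares its locus, were lower.

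Sterol synthesis genes had their largest median in SRSF6-OE among the 5 contrasts with Control, at 1.23 with 20 of 21 members higher (camera adjusted p = 8.2e-16, and adjusted p = 0.482 with an estimated correlation). DHCR7 (2.49 ± 0.45), INSIG1 (2.30 ± 0.47) and SQLE (1.67 ± 0.28) passed in DESeq2, which called 13 members, against 0 in edgeR over all genes and 15 adjusted over the list alone. Mitotic genes were higher in 30 of 30 (median 1.46, camera adjusted p = 1.4e-09, with MKI67 at 144 ± 8.17 against 41.4 ± 34.1 CPM), DNA replication genes in 25 of 26 (median 0.97, camera adjusted p = 5.5e-08) and ribosome biogenesis genes in 26 of 27 (median 0.48, camera adjusted p = 7.2e-08). These 3 lists had adjusted p = 0.704 with an estimated correlation. The mean log2 CPM of replication genes was 4.89 in the summed SRSF6-OE library against 3.13 in the summed Control library. It was 4.18 in SRSF6-OE replicate 3 against 4.01 in Control replicate 3. For mitotic genes these values were 5.93 against 3.70 and 5.44 against 4.95, so the rise lay mostly in the summed libraries. Glycolysis and hypoxia genes were higher in 23 of 27 members (median 0.76, camera adjusted p = 4.7e-06), among them LDHA (1.91 ± 0.51), VEGFA (1.98 ± 0.72) and GPI (0.92 ± 0.18), and unfolded protein response genes in 25 of 29 (median 0.73, camera adjusted p = 2.7e-04). Both lists had adjusted p = 0.704 with an estimated correlation. Matrix protease genes were higher in 20 of 23 (median 1.04, camera adjusted p = 1.8e-05, and adjusted p = 0.704 with an estimated correlation), with ADAM8 at 44.6 ± 25.2 against 5.07 ± 0.071 CPM. Cornification genes were higher in 21 of 28 (median 1.71, camera adjusted p = 0.017), basement membrane genes in 15 of 22 (median 0.29, camera adjusted p = 0.021, with LAMA5 at 0.76 ± 0.23) and immediate early and EGFR feedback genes in 21 of 28 (median 0.95, camera adjusted p = 0.018). Their adjusted p was 0.772, 0.746 and 0.773 with an estimated correlation. The only immediate early member that DESeq2 called, ATF3, was lower. Interferon-stimulated genes were lower in 30 of 34 (median -0.78, camera adjusted p = 6.1e-06, IFI44 -1.96 ± 0.60 and IFI27 -1.86 ± 0.42), MHC class I genes in 8 of 9 (median -0.42, camera adjusted p = 0.021) and histone genes in 10 of 10 (median -1.02, camera adjusted p = 0.0022, HIST1H2AC -1.31 ± 0.29). All 3 lists had adjusted p = 0.704 with an estimated correlation. Adjusted over the list alone, edgeR passed 10 interferon-stimulated, 7 glycolysis and hypoxia, 6 DNA replication, 3 histone and 2 ribosome biogenesis genes and 0 mitotic genes, against 0 over all genes and 8, 7, 7, 2, 3 and 4 in DESeq2. Of the interferon-stimulated genes, 1 of the 10 and 1 of the 8 were higher than Control.

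STARD13-AS was the sole edgeR call of 21326 genes for SRSF6-OE against Control, with 4154 genes at an unadjusted p under 0.05. Limma-voom called 30, DESeq2 called 752 genes higher and 380 lower, and edgeR on 18 separate samples called 2411 and 1619. The STARD13-AS call was lost (count 0) without Control replicates 1-2, without Control replicate 3 and without SRSF6-OE replicate 3, at log2 fold changes of 9.32, 9.11 and 7.30, against 10.58 without SRSF6-OE replicates 1-2. It was also lost without any 1 of the 8 libraries labelled SRSF2-OE, SRSF4-OE or SRSF9-OE, at 9.13 to 9.23 (edgeR adjusted p = 0.056 to 0.128). The gene was not tested under a stricter filter on low counts. As for SRSF4-OE, a fit of only the 4 libraries compared has far fewer residual degrees of freedom than the main fit. The edgeR count was 2 without SRSF6-OE replicates 1-2, 48 without TRA2B-OE replicates 1-2, 34 without TRA2B-OE replicate 3, 48 without the libraries labelled SRSF2-OE replicate 1 and TRA2B-OE replicate 3, and 156 when only the 4 libraries compared were fitted.

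In the libraries labelled SRSF9-OE, SRSF9 itself (adjusted p = 7.2e-11) was followed by GATC, which overlaps SRSF9 on the opposite strand (262 ± 105 against 72.8 ± 4.43 CPM, log2 fold change 1.82 ± 0.31), and by the RNA helicase gene DDX55 (0.58 ± 0.12) among DESeq2 calls, with ATF3 lower (-3.29 ± 0.94). Whether reads were counted by strand is not given in the sources used here, so counts of SRSF9 and GATC may share reads. Sterol synthesis genes lay above Control in 20 of 21 members (median 0.50, camera adjusted p = 1.2e-09), ribosome biogenesis genes in 27 of 27 (median 0.44, camera adjusted p = 1.1e-12) and DNA replication genes in 25 of 26 (median 0.42, camera adjusted p = 1.5e-04). Their adjusted p was 0.704, 0.704 and 0.772 with an estimated correlation. Mitotic genes were higher in 29 of 30 but without a camera call (median 0.38, adjusted p = 0.125). In the mean log2 CPM of mitotic and replication genes, SRSF9-OE replicate 3 (3.78 and 3.57) lay below Control replicate 3 (4.95 and 4.01), and SRSF9-OE replicates 1 and 2 above it. Matrix protease genes (16 of 23 higher, median 0.59), immediate early and EGFR feedback genes (20 of 28, median 0.83), cornification genes (20 of 28, median 0.60), glycolysis and hypoxia genes (20 of 27, median 0.35) and unfolded protein response genes (24 of 29, median 0.46) had camera adjusted p = 0.0024, 0.0044, 0.044, 0.015 and 0.017. Their adjusted p was 0.704, 0.762, 0.807, 0.772 and 0.773 with an estimated correlation. The only immediate early or unfolded protein response member that DESeq2 called was ATF3, which is on both lists and was lower. The SR list (9 of 13 higher, median 0.25, camera adjusted p = 2.7e-04, and adjusted p = 0.482 with an estimated correlation) holds SRSF9. Interferon-stimulated genes were lower in 28 of 34 (median -0.38, camera adjusted p = 0.0021), MHC class I genes in 7 of 9 (median -0.38, camera adjusted p = 0.036) and junction genes in 20 of 25 (median -0.25, camera adjusted p = 0.0063), each with adjusted p = 0.704 with an estimated correlation.

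No gene passed edgeR's test for SRSF9-OE against Control (0 of 21326, smallest adjusted p = 0.158), and 954 had an unadjusted p under 0.05, fewer than the 1066 expected by chance. DESeq2 called 12 genes higher and 1 lower, fewer than the median of 23.5 it called in 10 simulated sets without change. That median pools the 5 contrasts and covers only the 21326 filtered genes, while DESeq2 adjusted over 25766 genes here. EdgeR on 18 separate samples called 5 and 0, and limma-voom called 0. Adjusted over the list alone, edgeR passed 2 SR genes and 1 gene of the leukocyte list and none in the other 28 lists. The edgeR count was 2 without SRSF9-OE replicate 1, and 1 with the label set left out or with only the 5 libraries compared.

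In the libraries labelled TRA2B-OE, FDPS, which encodes farnesyl diphosphate synthase of the sterol pathway, rose from 123 ± 24.1 CPM in Control to 517 ± 37.0 CPM (n = 2), a log2 fold change of 2.10 ± 0.21. RUSC1-AS1, an antisense RNA gene that overlaps FDPS, rose from 67.5 ± 7.07 to 273 ± 8.23 CPM, a log2 fold change of 2.03 ± 0.19, and the 2 may share reads. Both had an edgeR adjusted p = 0.013. The rise was not particular to TRA2B-OE: DESeq2 called both genes higher in 4 of the 5 contrasts with Control. No direct contrast of TRA2B-OE with another overexpression group gave an edgeR call. The protease inhibitor gene TIMP1 (416 ± 69.1 against 91.5 ± 38.9 CPM), FADS2 (log2 fold change 2.87 ± 0.53) and the cell cycle genes MYBL2 (2.73 ± 0.70) and CCNA1 (3.19 ± 1.25) were higher in DESeq2. PSG4 (-4.98 ± 1.28), the matrix gene POSTN (-4.91 ± 1.11), ATF3 (-4.14 ± 0.95), APOE (-3.20 ± 1.05) and BIRC3 (-1.89 ± 0.30) were lower.

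All 21 sterol synthesis genes measured lay above Control in TRA2B-OE (median 1.10, camera adjusted p = 2.4e-23, and adjusted p = 0.482 with an estimated correlation), with MVD at 2.04 ± 0.32, INSIG1 at 2.02 ± 0.47 and DHCR7 at 2.01 ± 0.45. EdgeR called 1 of them over all genes (FDPS) and 15 adjusted over the list alone, and DESeq2 called 11. Mitotic genes were higher in 30 of 30 (median 1.49, camera adjusted p = 5.1e-16), DNA replication genes in 26 of 26 (median 1.01, camera adjusted p = 2.8e-16, with RRM2 at 2.58 ± 0.78 and CDC45 at 2.49 ± 0.60), ribosome biogenesis genes in 26 of 27 (median 0.40, camera adjusted p = 6.7e-09), hnRNP genes in 17 of 22 (median 0.15, camera adjusted p = 0.048, HNRNPAB 0.77 ± 0.16) and NRF2 target genes in 16 of 20 (median 0.47, camera adjusted p = 5.2e-04). All 5 lists had adjusted p = 0.704 with an estimated correlation. The NRF2 targets include TALDO1 (0.89 ± 0.15) of the pentose phosphate pathway and AKR1C1 (1.58 ± 0.44). Matrix protease genes were higher in 16 of 23 (median 0.31, camera adjusted p = 0.041) and mitochondrially encoded genes in 11 of 13 (median 0.44, camera adjusted p = 0.050), with adjusted p = 0.773 and 0.822 with an estimated correlation. In each of these lists a single library stood apart. The mean log2 CPM of matrix protease genes was 5.53 in the summed TRA2B-OE library against 3.82 in the summed Control library, but 4.17 in TRA2B-OE replicate 3 against 4.16 in Control replicate 3. Mitochondrially encoded genes took 14.3% of counts in TRA2B-OE replicate 3 against 7.64% in Control replicate 3, but 9.18% in the summed TRA2B-OE library against 11.96% in the summed Control library. Lower were genes of apoptosis regulators (17 of 24, median -0.13, camera adjusted p = 0.036), epithelial junctions (17 of 25, median -0.16, camera adjusted p = 0.016, CLDN1 -2.57 ± 0.75) and the fibroblast marker list (5 of 8, median -0.69, camera adjusted p = 0.050). All 3 had adjusted p = 0.704 with an estimated correlation. The apoptosis members lower in DESeq2 were BIRC3, an inhibitor of apoptosis, and HRK (-3.12 ± 0.81), which promotes it. Adjusted over the list alone, edgeR passed 8 DNA replication, 4 ribosome biogenesis and 4 NRF2 target genes and 0 mitotic genes, against 0 over all genes and 5, 2, 4 and 0 in DESeq2.

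FDPS and RUSC1-AS1 were the 2 edgeR calls of 21326 genes for TRA2B-OE against Control, with 2559 genes at an unadjusted p under 0.05. Limma-voom called 55, DESeq2 called 264 genes higher and 174 lower, and edgeR on 18 separate samples called 1676 and 1221. Both calls were lost (count 0) without Control replicates 1-2, without Control replicate 3, without TRA2B-OE replicates 1-2, with the label set left out, with the numeric-labelled libraries only and when only the 4 libraries compared were fitted. In the first 4 of these fits the log2 fold changes were 1.76 to 2.12 for FDPS and 1.77 to 2.13 for RUSC1-AS1, lowest without TRA2B-OE replicates 1-2. Both were also lost without SRSF9-OE replicate 3 (2.10 and 2.03, edgeR adjusted p = 0.052). The count was 14 without TRA2B-OE replicate 3, 6 with a stricter filter and 12 with none.

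**Figure D3:**
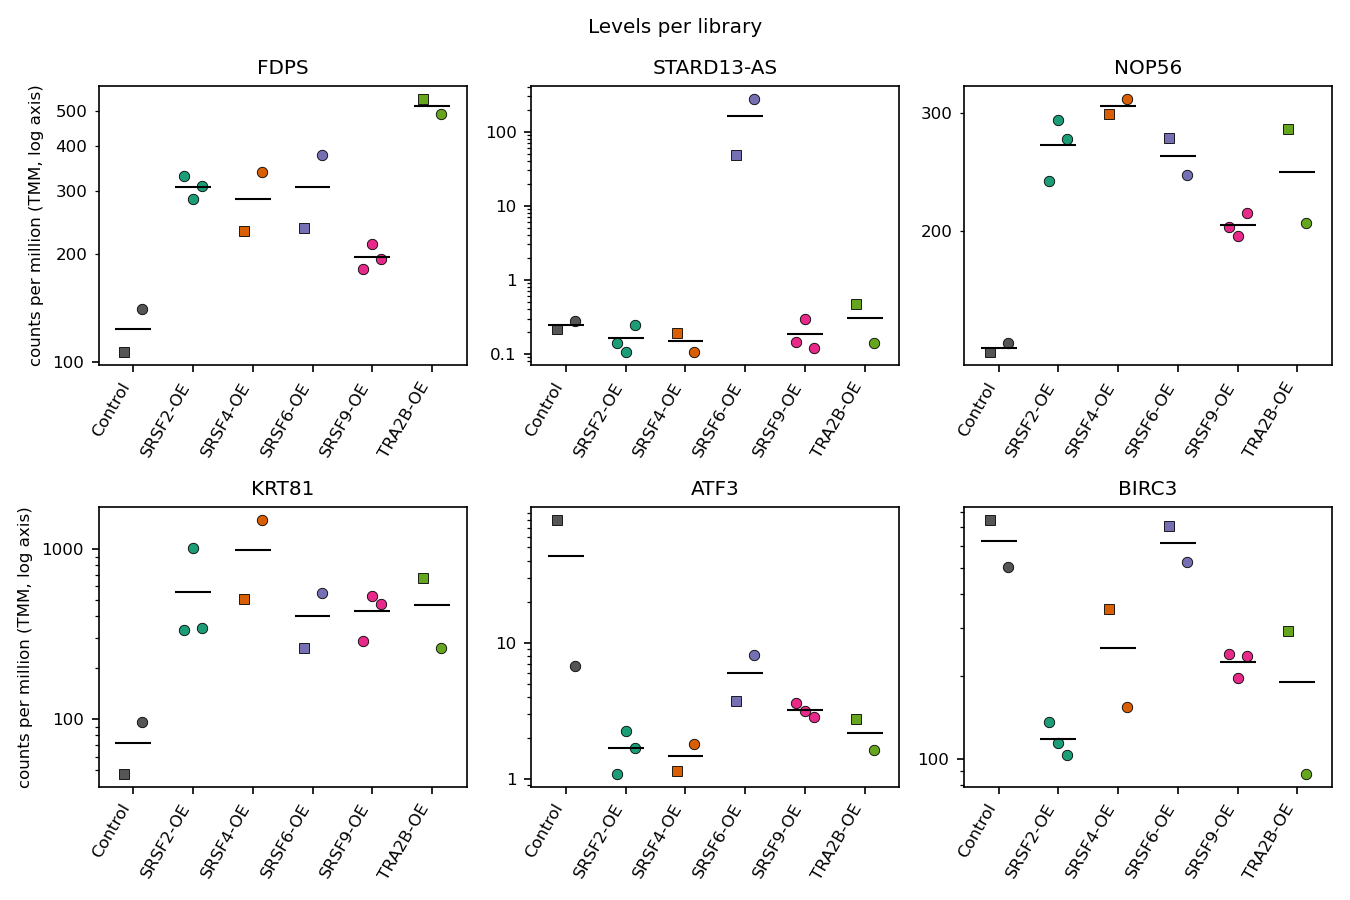
CPM (y axis, log scale) of 6 genes chosen after their values were seen, in the 14 libraries by label (x axis). Circles are libraries of 1 sample, squares are libraries summed over 2 lanes and horizontal lines are means; FDPS is highest in TRA2B-OE (517 CPM), STARD13-AS is above 1 CPM in SRSF6-OE alone, and the Control libraries of ATF3 lie far apart (79.3 and 6.71 CPM).

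Over the 5 contrasts, camera called 58 of 150 list tests, 43 up and 15 down, but 0 with an estimated correlation (smallest adjusted p = 0.482, 7 at an unadjusted p under 0.05) and 0 with fry (smallest adjusted p = 0.097). Sterol synthesis, DNA replication and ribosome biogenesis were called up by camera in all 5 contrasts. Several lists had no camera call in any contrast. Their median log2 fold changes ran from -0.16 to 0.05 for SR protein kinases and other splicing regulators, from -0.07 to 0.01 for p53 targets, from -0.12 to -0.01 for cytosolic ribosomal proteins, from -0.17 to 0.36 for mesenchymal genes of EMT, from -0.08 to 0.25 for basal and from -0.33 to 0.10 for luminal mammary markers. Among markers of other cell types, 6 of 11 genes of the endothelial list were measured, with medians of 1.0 to 1.36 and a camera call in SRSF9-OE (4 of 6 higher, adjusted p = 0.039, and adjusted p = 0.704 with an estimated correlation). In that contrast, and named after their values were seen, ENG stood at 43.1 ± 13.2 against 19.0 ± 7.11 CPM and TEK at 4.82 ± 4.25 against 0.146 ± 0.044 CPM, while KDR, the VEGF receptor, was lower at 9.42 ± 3.06 against 23.1 ± 4.29 CPM. The leukocyte list (6 of 13 measured) had medians of -1.08 to -0.07 and no call, although CD14 was higher in all 5 groups (1.16 ± 0.22 CPM in Control, 3.41 to 4.87 CPM elsewhere, DESeq2 adjusted p = 2.4e-04 to 0.073). Over the 150 list tests, the median, the mean and the direction of camera differed in sign in 18, of which 0 carried a camera call.

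**Figure D4:**
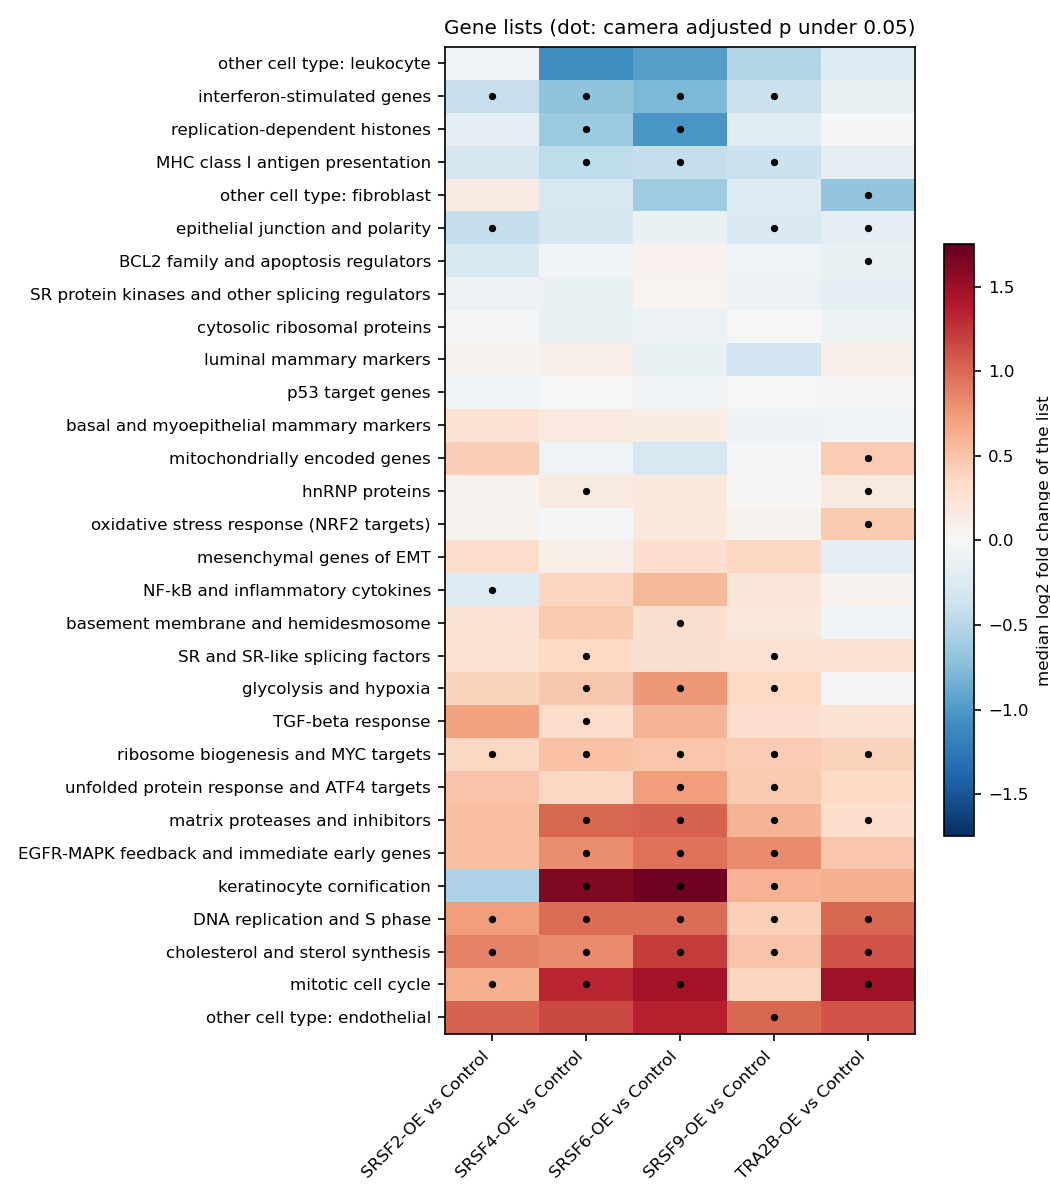
Median log2 fold change against Control (colour) of the 30 gene lists (y axis) in the 5 contrasts (x axis), with a dot where camera with its preset correlation gave an adjusted p under 0.05. Of the 58 dots, sterol synthesis, DNA replication and ribosome biogenesis (higher) have 5 each, mitotic and matrix protease genes (higher) and interferon-stimulated genes (lower) 4 each, and the rest lie on other lists; with an estimated correlation there would be 0.

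The overexpression groups were then compared with one another, without Control. SRSF9 was high in SRSF9-OE (above). STARD13-AS, the long non-coding RNA AC105460.1 (11.2 ± 14.5 CPM), the organic anion transporter gene SLCO1B3 (3.80 ± 2.54 CPM), the bile salt export pump gene ABCB11 (2.79 ± 0.071 CPM) and PCDHGA11 (1.78 ± 0.320 CPM) were highest in SRSF6-OE, where the other overexpression groups held at most 0.302, 0.035, 0.221, 0.091 and 0.321 CPM. PCDHGA11 belongs to a protocadherin cluster whose members share exons, so its counts are uncertain. ADARB2, an RNA editing enzyme homologue, stood at 2.47 ± 1.17 CPM in SRSF6-OE and 1.73 ± 0.212 CPM in SRSF9-OE against 0.104 ± 0.058 CPM in SRSF2-OE. MIS18A-AS1, antisense to MIS18A, was 3.41 ± 1.32 CPM in SRSF9-OE and at most 0.302 CPM in the other overexpression groups. These 8 genes passed edgeR's F test over the 5 groups (adjusted p = 7.4e-04 to 0.050), LINC01322 was next (adjusted p = 0.070), 2355 genes had an unadjusted p under 0.05, DESeq2 called 866 and limma-voom 5. In SRSF9-OE replicates 2 and 3, MIS18A-AS1 stood apart together with SRSF9, GATC and SRSF9P1, the last named after its values were seen. Counts of MIS18A-AS1 may therefore hold shared reads, which was not tested. The F test count ran from 0 without SRSF6-OE replicate 3 to 54 without SRSF2-OE replicate 1, and was 0 with a stricter filter on low counts.

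Direct contrasts between pairs of overexpression groups gave 12 edgeR calls in all, whose genes are named after their values were seen. SRSF2-OE was lower than SRSF6-OE in 5 genes (FRAS1, AC105460.1, ADARB2, SLCO1B3 and STARD13-AS), SRSF6-OE differed from SRSF9-OE in 5 (AC105460.1, PCDHGA11, SLCO1B3 and STARD13-AS higher, SRSF9 lower), SRSF4-OE from SRSF6-OE in STARD13-AS and SRSF2-OE from SRSF9-OE in SRSF9. The other 6 pairs gave 0 calls in edgeR, with 744 to 2769 genes at an unadjusted p under 0.05. DESeq2 called 1938 over the 10 pairs, the most for SRSF2-OE against SRSF6-OE (294 higher, 549 lower) and few for SRSF4-OE against SRSF9-OE (2 higher, 20 lower). The edgeR total was 785 without SRSF6-OE replicates 1-2, 338 without TRA2B-OE replicates 1-2, 252 without TRA2B-OE replicate 3 and 166 without SRSF2-OE replicate 1. It fell to 1 without SRSF2-OE replicate 3 or SRSF9-OE replicate 2, to 2 without SRSF6-OE replicate 3 or SRSF9-OE replicate 3, and to 3 without SRSF2-OE replicate 2 or either SRSF4-OE library.

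Many DESeq2 calls recurred across contrasts that share the Control libraries. SRSF4-OE and SRSF6-OE had 168 genes higher and 112 lower in common, where 11.3 and 4.9 are expected of independent lists and 3.3 and 1.0 were found in simulated unchanged groups. The simulated contrasts had a median of 23.5 calls, far fewer than the 557 and 1132 called here, and their genes were drawn independently. The simulated overlaps therefore do not show what a shift of many genes in a shared Control library would give. The 4 pairs with SRSF9-OE shared 1 to 5 higher genes, against 3.0 to 5.8 in the simulated sets. In all, 50 genes were higher and 21 lower in at least 4 contrasts. Among these, 1 in each direction (AC097451.1 and ATF3, named after their values were seen) was called in all 5. Over the 10 pairs 3 calls went in opposite directions. The correlation of log2 fold changes across genes was 0.473 to 0.755 (median 0.595) against 0.489 to 0.652 (median 0.497) in the simulated sets. It lay below the simulated value for SRSF2-OE with SRSF6-OE (0.473 against 0.50) and with SRSF9-OE (0.589 against 0.652). The covariance had a median of 0.392 against 0.171. The covariance exceeded the simulated value in 10 of 10 pairs, by 0.073 (SRSF2-OE and SRSF9-OE) to 0.486 (SRSF4-OE and SRSF6-OE). With 2 Control libraries these could not be split, and the simulated values hold no shifts shared by many genes. Part of the excess may therefore come from the shared controls.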

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

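Alternatives chosen only after the data were seen were those without the libraries labelled SRSF2-OE 1 and TRA2B-OE 3, the numeric-labelled libraries only, DESeq2 on separate samples, separate samples without the label set or with the replicate block, the list tests without single libraries, RLE, only the groups compared and single libraries left out for the introduced factors, libraries of other groups left out, and every alternative for the direct contrasts and the similarity of changes. The order of contrasts in the counts of genes called is SRSF2-OE, SRSF4-OE, SRSF6-OE, SRSF9-OE and TRA2B-OE against Control, then the F test, against 0, 0, 1, 0, 2 and 8 as reported. RLE normalisation gave 0, 0, 1, 0, 2 and 8. No filter on low counts gave 2, 3, 5, 2, 12 and 34, and a stricter filter 0, 0, 0, 0, 6 and 0 (STARD13-AS was then not tested). The label set left out gave 0, 0, 1, 1, 0 and 8, the numeric-labelled libraries only 0, 0, 1, 0, 0 and 5, only the groups compared 0, 2504, 156, 1, 0 and 3, and a fold threshold of 1.5 gave 0, 0, 1, 0 and 2. Every deposited sample as its own replicate gave 1345, 3465, 4030, 5, 2897 and 1001, where lanes of a library count as replicates, 3474, 2141, 2621, 30, 1822 and 762 without the label set as well, and 3874, 2217, 2623, 26, 1823 and 908 with the replicate block in its place. DESeq2 gave 451, 557, 1132, 13, 438 and 866, DESeq2 on separate samples 2401, 4548, 5178, 236, 3924 and 3505, and limma-voom 0, 0, 30, 0, 55 and 5. Without the libraries labelled SRSF2-OE 1 and TRA2B-OE 3, counts were 46, 88, 48, 0, 2 and 57. Leaving out any 1 of the 14 libraries gave 0 to 69, 0 to 24, 0 to 48, 0 to 2, 0 to 14 and 0 to 54. Where this left a group with 1 library, that library was assumed to vary like the other groups. Apart from the separate samples, the cause of these differences was not tested.

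For the introduced factors, SRSF2, SRSF4, SRSF9 and TRA2B kept their direction in the own group under every alternative run, and SRSF6 under all but one: it was -0.014 without Control replicate 3, and up to 0.35 without another library. SRSF9 ran from 2.40 to 2.98 when a library of the groups compared was left out. Those that passed the threshold under an alternative were SRSF9 without a filter (2.71), without the label set (2.70), without SRSF9-OE replicate 1 (2.98), on separate samples (2.71) and in DESeq2 (2.71, or 2.70 on separate samples), SRSF4 on separate samples (1.09), without the libraries labelled SRSF2-OE 1 and TRA2B-OE 3 (1.11), with only the groups compared (1.12) and in DESeq2 (1.12, or 1.08 on separate samples), TRA2B on separate samples (0.79) and in DESeq2 (0.72, or 0.79 on separate samples), and SRSF2 on separate samples (0.81, or 0.80 in DESeq2). The cause was not tested. The 58 list calls became 0 with an estimated correlation and 0 with fry, and stayed between 48 and 65 otherwise. The 12 direct calls became 28 without the label set, 2515 on separate samples, 1938 in DESeq2 and 1 to 785 when a library was left out. The median correlation of changes, 0.595, was 0.651 without Control replicates 1-2 and 0.764 without Control replicate 3. Of 1518 values for 185 pairs of a named gene and a contrast, 1144 kept direction and side of the threshold, 344 passed it newly, 24 lost it and 6 changed sign. The 6 were all SRSF6, at no point called: in TRA2B-OE, -0.010 without a filter, -0.023 without the label set, -0.057 on separate samples and -0.14 without the libraries labelled SRSF2-OE 1 and TRA2B-OE 3, and in SRSF9-OE, -0.21 without the label set and -0.088 with the replicate block.

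The replicate numbers did not clearly pair the libraries: deviations of libraries with the same number correlated at -0.42 to 0.494, with a median of 0.119, and 16 of 31 such pairs were over 0.1, against a median of -0.116 and 17 of 50 pairs for other numbers. Pairs of the same label set had a median of 0.022 with 22 of 45 over 0.1, and other pairs -0.071 with 11 of 36. These values cannot weigh the label set against the replicate numbers. Deviations were taken from the group mean, and all SRSF2-OE and SRSF9-OE libraries carry numeric labels. In the other 4 groups both splits are the same. On principal component 2 the 4 summed libraries lay at 41.0 to 54.4 and the other 10 at 7.12 or below. Of the 14 libraries, 6 deviated most like a library of their own number. With the replicate block in place of the label set, counts were 0, 0, 0, 0, 0 and 5, with 62 list calls and 3 direct calls. STARD13-AS, FDPS and RUSC1-AS1 were then no longer called, at log2 fold changes of 9.23, 2.09 and 2.03 (edgeR adjusted p = 0.085, 0.10 and 0.10). Splitting the Control libraries was not run, since there are 2. Depth limits genes such as MMP10 and AC105460.1, whose Control libraries hold few counts or none.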

Other observations

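The tests chosen only after the result was seen were every label swap for SRSF6, both wrong-label tests, the fit with the mitochondrial share, the count over all 30 lists and every comparison of genes that set libraries apart.

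Control stood apart from all 12 overexpression libraries in 6 genes at a 2-fold limit, named after their values were seen. The melanosome and lysosome glycoprotein gene GPNMB (447 and 610 CPM in Control, 4.11 to 205 CPM elsewhere), the mechanosensitive channel gene PIEZO2 (7.63 and 12.4 CPM, elsewhere 0.129 to 3.49 CPM) and ACSS1, a mitochondrial acetyl-CoA synthetase gene (10.1 and 14.9 CPM, elsewhere 0.277 to 4.85 CPM), were lower in the overexpression libraries. KRT81 (47.5 and 96.1 CPM, elsewhere 260 to 1471 CPM), OSBP2 (12.6 and 13.8 CPM, elsewhere 27.9 to 146 CPM) and AC002401.4 were higher. Of the 91 ways to choose 2 of the 14 libraries, 9 others gave as many genes, up to 31, so the number by itself does not set Control apart.

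Some genes followed libraries across labels. BST2, ZNF22, CNTN3 and HLA-B were low in both SRSF4-OE libraries and in SRSF2-OE replicates 2 and 3 but not in SRSF2-OE replicate 1: BST2 held 0.417 to 1.51 CPM in the first 4 and 38.7 CPM in the last, against 28.2 and 43.4 CPM in Control. Genes at least 1.5-fold apart from the other 12 libraries in the same direction numbered 91 for the pair SRSF2-OE 2 and SRSF6-OE 3, 80 for SRSF2-OE 1 and TRA2B-OE 3, and 66 for the summed SRSF6-OE and TRA2B-OE libraries. Pairs of the same label gave 36 for SRSF6-OE, 30, 9 and 0 for SRSF2-OE, 26 for Control, 14, 0 and 0 for SRSF9-OE, 8 for SRSF4-OE and 5 for TRA2B-OE. At a 3-fold limit the first 3 pairs gave 2, 3 and 13, the SRSF6-OE pair 12 and the other same-label pairs at most 1.

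Camera called 6 lists the same way in at least 4 of the 5 contrasts with Control: sterol synthesis, DNA replication, ribosome biogenesis, mitotic and matrix protease genes up, and interferon-stimulated genes down, although 0 of these calls held with an estimated correlation or with fry. Without Control replicates 1-2, the medians kept 0.711 of their size (0.471 against 0.662 log2 units). This argues against that library as the whole source, although the lists were picked for calls that also used Control replicate 3. Control differed from the other 12 libraries in 5 of the 6 lists by an exact two-sided permutation test over 91 choices (p = 0.011 to 0.044, mitotic genes 0.077), and after adjustment in 2 (sterol synthesis and ribosome biogenesis, 0.033, the others 0.053 to 0.077), but this test is void because the lists were picked for calls against the same 2 libraries. Over all 30 lists, 8 of the 91 choices of 2 libraries gave at least the 5 lists that Control gave, up to 8, so a chance order of the libraries may account for the pattern and stays open. So does a response common to overexpressed factors, which the 2 Control libraries cannot settle. The mitochondrial share averaged 9.80% in Control and 9.82% elsewhere, which argues against a linear effect of it as the source. With it in the fit the differences kept 0.996 of their size (median), which such close means made likely beforehand. That 5 of 6 lists stayed over 2 SE is no support, since the lists were picked for calls against Control. The planned test was inconclusive: the scores had a median absolute Spearman rho of 0.376 with the share (-0.521 to 0.495), between the limits set beforehand.

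SRSF6 was not detectably higher in the libraries labelled SRSF6-OE than in Control. A swap with SRSF4-OE or SRSF9-OE libraries would bring their factor along, but SRSF4 and SRSF9 reached at most 1.41 times the Control library of the same label set, below the lowest value of 1.96 for SRSF4 and 3.88 for SRSF9 in their own libraries. SRSF2-OE 2 and 3 and the summed TRA2B-OE library held their own factor at 2.25, 1.76 and 1.90 times Control. These values lay above all libraries of other labels (at most 1.41 and 1.60), which argues against a swap with those libraries. SRSF2 reached at most 1.31 in the SRSF6-OE libraries, below SRSF2-OE 2 and 3 but above the 1.21 of SRSF2-OE 1 itself. That argues against a swap with SRSF2-OE 1 only if a swapped library held as much SRSF2 as SRSF2-OE 2 and 3. SRSF6 stood at 1.28 in SRSF2-OE 1, above both SRSF6-OE libraries but below SRSF2-OE 3 and SRSF4-OE 3. A swap with TRA2B-OE 3 may remain possible, since TRA2B reached 1.46 in SRSF6-OE and up to 1.60 under other labels, and SRSF6 stood at 1.19 in TRA2B-OE 3 against 1.04 and 1.19 in SRSF6-OE, 1.72 in SRSF2-OE 3 and 1.47 in SRSF4-OE 3. Lost or silent construct expression, and endogenous SRSF6 lowered by its own product, were not tested.

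TRA2B-OE replicate 3 and SRSF2-OE replicate 1 lay next to each other. A single library under both labels is argued against by a mean chi-square per gene of 31.5 between them, where lane pairs had at most 9.06. The other 14 pairs of samples within a group had 58.8 to 318, so these 2 libraries lay nearer to each other than any of those. A wrong construct label may apply to either: TRA2B stood at 147 CPM in the former, within the 105 to 168 CPM of 11 libraries of other labels, and SRSF2 at 214 CPM in the latter, within the 176 to 272 CPM of 10, each time without the other library of this pair. The high mitochondrial shares of both (14.3% and 16.4%) leave a shared state of the cultures or RNA open, and no biological explanation was tested.

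For SRSF2-OE against SRSF9-OE, 2 of the 10 splits of the 6 libraries called as many genes as the real split, itself included. The real split called 1 and the highest other 3, and 10 splits are too few for a share under 0.05.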
